A study of Mus musculus with 8 samples.

How the data were processed

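Expression was measured in 8 RNA-seq libraries, 2 each of CLP, ChILP, PD-1+ and CCR6+ progenitors from the marrow of C57BL/6 mice. Per the labels' protocols, sorted cells were lysed directly, total RNA was extracted, libraries were made with Smart-seq2, a method that amplifies full-length polyadenylated transcripts from few cells, and reads of 50 bp were generated. The submitters' processing notes name CASAVA 1.8.4, Bowtie2 2.2.2 and the mouse build mm9, with no role or order. The read counter, its strand setting, the annotation release and the handling of duplicates and shared reads are not given in the sources used here. Smart-seq2 amplifies before counting and these libraries carry no molecular identifiers here, so counting intervals and floors cover counting error only.

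The authors deposited 1 table per library with 29257 RefSeq transcripts, each with a whole-number read count, an RPKM value and a transcript length. Per the values of the deposited tables, RPKM is the count divided by length and by 1 library total, with no other scaling. The tables hold 22878 gene symbols, 4019 of them with more than 1 transcript, and isoforms of a gene share reads. Each gene was therefore represented by the transcript with the largest mean count over the 8 libraries, and its identifier is printed. The longest transcript differs for 545 genes and was used as an alternative. For 337 symbols an accession lies at more than 1 locus and 1106 genes have the same counts in all libraries as another gene; such copies, Hba-a1 among them, are uncertain. Strand is not given, so reads of antisense partners cannot be told apart. No coordinates are printed. Per gene, reads summed to 7685188 to 13997897 per library.

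Groups were taken from the labels. The comparisons were ChILP against CLP and PD-1+ against CCR6+, as stated in the study's design. The tests, the samples in each fit, 21 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr with a minimum count of 10, robust quasi-likelihood F test, two-sided) with all 4 groups in 1 fit, since each has only 2 libraries; 13619 genes passed the filter. The common biological coefficient of variation was 0.526, with 4 residual degrees of freedom and a median of 3.93 prior degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes. For each list the same p-values were also adjusted over the list alone; such a count is weaker evidence than one over all genes. Sets were tested with camera in limma 3.58.1 (preset correlation 0.01, and again with an estimated correlation) and with fry, which tests whether a list's genes move on balance 1 way without comparing them with other genes; lists with at least 5 measured genes were tested and adjusted over the lists of a comparison. Log2 fold changes and SE come from edgeR, and means and SD of levels from the deposited RPKM. Where a group had no read, the fold is a lower bound against 3 counts over the group; where it had 1 to 3 reads, a ratio of pooled rates with an exact (Clopper-Pearson) 95% interval is given.

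The lists covered the sort gate, ILC progenitor regulators, B lineage, stem and multipotent progenitor, myeloid progenitor, plasmacytoid and dendritic, LTi and ILC3, ILC2, ILC1 and NK, T lineage, Notch target, chemokine receptor and homing, cytokine receptor, inhibitory and costimulatory receptor, effector cytokine, MHC class II, proliferation, erythroid and megakaryocyte, mast cell and basophil, plasma cell and mature B, and immediate early and stress genes. Some genes stand in several lists. The rule named the gate genes, Gata3, Id2, Zbtb16, Tcf7, Tox, Nfil3, Rora and Bcl11b always, up to 8 called genes per direction with the largest changes among those with a mean of at least 10 RPKM in the higher group and no overlap between libraries, and up to 4 called members of each list. Since few genes were called over all genes, list members called over their list alone and genes called by DESeq2 are named as well; those were chosen after their values were seen. Another gene that the rule names is not reported here.

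Alternatives fixed beforehand were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma on log2(RPKM + 1) and log2(RPKM + 0.1) of genes with at least 1 RPKM in 2 libraries, no filter, a filter of 5 RPKM in 2 libraries, only the 4 libraries compared, a replicate block, a 2-fold limit, an adjusted p under 0.01 and leaving out each library in turn; the lone library then left is assumed to vary like the other groups. Chosen after seeing the data were the longest transcript, voom with library quality weights, the 4 libraries with a replicate block, a covariate for mature myeloid transcripts, leaving out genes at several loci, leaving out both number 2 libraries of PD-1+ and CCR6+ cells, and other gene sets for the overlap and the position, with tests of direction for the overlap. Counts simulated from the real means, the library sizes and the dispersion that edgeR fitted to each gene, with 200 genes changed, were used to check the scripts. Drawing from edgeR's dispersions can favour edgeR over DESeq2, and the share of wrong calls depends on how many genes are changed. For ChILP against CLP edgeR recovered 42.2% of genes changed 4-fold and 68.0% of those changed 16-fold, and DESeq2 58.0% and 78.2%. For PD-1+ against CCR6+ edgeR recovered 43.6% and 69.0% with 5.1% of calls wrong, and DESeq2 58.8% and 80.8%. A shifted list of 14 genes was called in 5 of 5 simulations with camera's preset correlation and in 3 of 5 with an estimated one, in each comparison. Interferon, neutrophil, red cell and progenitor marker lists were added after the data had been seen and are used only in the closing observations.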

Results

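Polyadenylated RNA was sequenced from 4 progenitor populations of mouse marrow (C57BL/6, an inbred strain), with 2 libraries per population. Innate lymphoid cells (ILCs) are lymphocytes that act without rearranged antigen receptors. They arise in the marrow from common lymphoid progenitors (CLP) through a committed stage named in the labels as the common helper-like innate lymphoid progenitor (ChILP). CLP were sorted as lineage-negative cells with CD127, Flt3, Sca-1 and Kit on their surface and without integrin α4β7. ChILP were sorted as lineage-negative cells with CD127, integrin α4β7 and Kit and without Flt3 or ST2. The other populations divided the ChILP gate: PD-1+ cells lacked CCR6, and CCR6+ cells lacked PD-1. The labels name PD-1+ cells as progenitors of ILCs other than lymphoid tissue inducer (LTi) cells, and CCR6+ cells as LTi progenitors. CLP and ChILP were enriched by depleting lineage-positive cells, while PD-1+ and CCR6+ cells were enriched by magnetic capture of cells bearing integrin α4β7, so the route of enrichment differs between these pairs of groups and is the same within each comparison below.

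Reads assigned to genes numbered 7685188 to 13997897 per library, and 13619 genes were tested. The labels do not say whether the 2 libraries of a group came from separate mice, so p-values measure the spread between these samples, which may be technical. Within groups the libraries differed by more than sampling noise, with a chi-square per gene of 42.8 for CLP, 68.4 for ChILP, 85.1 for PD-1+ and 43.3 for CCR6+ cells. The lowest value of all library pairs, 18.9, lay between PD-1+ replicate 2 and CCR6+ replicate 2. Transcripts of mature marrow cells set the groups apart by route of enrichment. Hba-a1 (NM_008218), an alpha globin whose reads cannot be told from those of its near-identical copy, stood at 3112 and 548 RPKM in CLP and at 4547 and 566 in ChILP, but at 21940.0 and 25450.0 in PD-1+ and 30610.0 and 25600.0 in CCR6+ cells. Lyz2 (NM_017372), a lysozyme of myeloid cells, stood at 356 to 1186 RPKM in the CLP and ChILP libraries and at 6387 to 14680.0 in the PD-1+ and CCR6+ libraries. Mpo (NM_010824), a granule enzyme of early myeloid progenitors, was arranged the other way, at 2816 to 4218 RPKM in CLP and ChILP and 201 to 529.8 in PD-1+ and CCR6+ libraries.

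**Figure D1:**
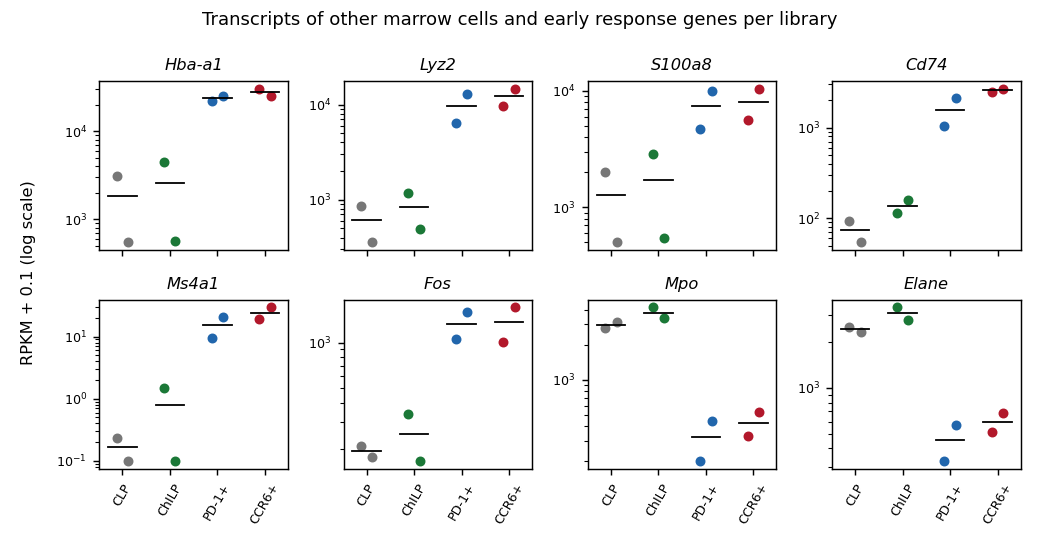
RPKM + 0.1 on a log scale of 8 genes in each library of the 4 groups; dots are single libraries and bars are group means. Hba-a1, Lyz2, S100a8, Cd74, Ms4a1 and Fos are higher in every PD-1+ and CCR6+ library than in any CLP or ChILP library, and Mpo and Elane are lower.

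The first comparison asked how the transcriptome changes from CLP to ChILP. ChILP carried a broad set of transcription factors of ILC development and had lower levels of B lineage transcripts. Gata3 (NM_008091), a factor required for ILCs and T cells, stood at 84.2 ± 46.8 RPKM in ChILP and 2.301 ± 0.623 in CLP (mean ± SD, n = 2 each, as for all values below). Tcf7 (NM_009331), which encodes TCF-1, stood at 80.3 ± 30.8 against 0.826 ± 0.396 RPKM, and Id2 (NM_010496), an inhibitor of the E proteins that drive B cell fate, at 277 ± 69.9 against 27.6 ± 0.389. Dntt (NM_009345), the template-independent DNA polymerase of antigen receptor rearrangement, stood at 63.7 ± 9.61 against 1133 ± 447 RPKM.

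Of all genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 3, 1 higher and 2 lower in ChILP, each with an adjusted p of 0.0495, and 792 had an unadjusted p under 0.05. Flt3 (NM_010229), the cytokine receptor used to sort the groups apart, fell from 124 ± 45.9 to 7.72 ± 3.71 RPKM (log2 fold change -3.94, SE 0.39). Cox6a2 (NM_009943), a subunit of cytochrome c oxidase, fell from 132 ± 42.2 to 9.32 ± 3.08 RPKM (log2 fold change -3.76, SE 0.39). Myo1e (NM_181072), an unconventional myosin, rose from 0.0654 ± 0.0144 to 4.13 ± 2.32 RPKM (log2 fold change 6.02, SE 0.60); it lies under the level set for named genes and was chosen after its values were seen. DESeq2 called 263 genes, 115 higher and 148 lower in ChILP, but on simulated data for this comparison, drawn with edgeR's dispersions, 34.8% of its calls were wrong, against 4.8% for edgeR. With the planned replicate block over all 8 libraries edgeR called 0. The edgeR count fell to 0 without CLP replicate 1, CLP replicate 2 or ChILP replicate 2 and rose to 24 without ChILP replicate 1; it was also 0 with DESeq2 size factors, where Flt3 and Cox6a2 had an adjusted p of 0.0513.

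Adjusted over the list alone (edgeR), 5 of the 9 gate genes changed. Pdcd1 (NM_008798, PD-1), Itgb7 (NM_013566) and Ccr6 (NM_001190333) rose, and Flt3 and Ly6a (NM_010738, Sca-1) fell. Pdcd1 stood at 81.9 ± 15.5 against 0.571 ± 0.357 RPKM. Ccr6 had no read in CLP and 6.02 ± 3.09 RPKM in ChILP, at least 79.1-fold higher with 3 counts over the CLP group as the floor (at least 50.4-fold without ChILP replicate 2). Itga4 (NM_010576), Kit (NM_001122733), Il1rl1 (NM_001025602, ST2) and Il7r (NM_008372, CD127) did not pass, with log2 fold changes of 0.54, 0.39, 0.44 and -0.09. The values of the genes other than Pdcd1 and Ccr6 check the sort and are not a finding. PD-1 and CCR6 only divided the ChILP gate, so the rise of Pdcd1 and Ccr6 is not such a check. Camera placed the list higher and fry lower in ChILP, and neither called it. Without CLP replicate 2, 1 gate gene rose and 2 fell.

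Of the 14 regulators of ILC progenitors, 12 rose in ChILP, adjusted over the list alone (edgeR), none fell, and none passed over all genes. The list's median log2 fold change was 3.94, and 3.14 to 4.81 leaving out 1 library in turn. Beside Gata3, Tcf7 and Id2, with log2 fold changes of 5.25 (SE 0.77), 6.63 (SE 0.86) and 3.38 (SE 0.48), the risers included Rora (NM_013646) at 121 ± 62.8 against 2.71 ± 0.664 RPKM, Zbtb16 (NM_001033324, PLZF, a marker of ILC precursors) at 22.7 ± 12.3 against 1.57 ± 1.01 and Tox (NM_145711) at 36.9 ± 18.1 against 5.11 ± 2.09. Bcl11b (NM_001079883), a factor of T cells and group 2 ILCs, had 3 reads in CLP, all in replicate 1, and 9.03 ± 5.304 RPKM in ChILP, a ratio of 583 (95% counting interval 199 to 2830.0), and of 353 without ChILP replicate 2. Tox2, Arg1, Maf, Ikzf2 and Ets1 also rose. Nfil3 (NM_017373), a factor that acts early in ILC development, stood at 12.5 ± 3.65 against 7.99 ± 1.503 RPKM and Runx3 at 18.2 ± 6.73 against 12.2 ± 0.191; neither passed. As a set the regulators were called with camera's preset correlation (adjusted p = 1.55e-18), but not with an estimated correlation (adjusted p = 0.0708).

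B lineage genes ran the other way. Of 18, 11 fell in ChILP, adjusted over the list alone (edgeR), and none rose, with a median log2 fold change of -2.49 (-4.58 without ChILP replicate 1). Blnk (NM_008528), an adaptor of pre-B cell receptor signalling, stood at 2.43 ± 0.229 against 54.2 ± 24.6 RPKM, Rag2 (NM_009020), a recombinase of antigen receptor genes, at 1.67 ± 1.26 against 24.1 ± 7.96, and Ebf1 (NM_007897) and Pax5 (NM_008782), the factors that fix B cell fate, at 0.902 ± 1.28 against 13.5 ± 4.29 and 0.136 ± 0.192 against 2.49 ± 0.0853. Of 16 stem and multipotent progenitor genes 3 fell (Cd93, Satb1 and Cd34), and of 12 plasmacytoid and dendritic cell genes 3 fell (Siglech, Tcf4 and the gate gene Flt3), again over each list alone. Their medians were -0.76 (-0.49 without CLP replicate 2 and -1.25 without ChILP replicate 2) and -0.45 (-0.64 to -0.50 leaving out 1 library in turn). Camera with a preset correlation called all 3 lists lower in ChILP (adjusted p = 4.92e-16, 2.01e-05 and 8.84e-04), and with an estimated correlation each had an adjusted p = 0.0527. The B lineage count was 6 without CLP replicate 1 and 7 without CLP replicate 2, and without ChILP replicate 2 1 rose and 8 fell. Without CLP replicate 1, 1 plasmacytoid and dendritic cell gene rose beside 3 that fell.

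Genes of several mature ILC fates were higher in ChILP, though the ILC2 list shares Gata3, Rora, Bcl11b and Arg1 with the regulators. The libraries are bulk, so whether the same cells carried genes of several fates was not tested. Adjusted over each list alone (edgeR), 9 of 15 LTi and ILC3 genes, 7 of 15 ILC2 genes and 5 of 25 ILC1 and NK cell genes rose; 2 of the last list fell. Ltb (NM_008518), a lymphotoxin subunit, stood at 205 ± 79.7 against 44.5 ± 6.902 RPKM and Cxcr5 (NM_007551), a chemokine receptor of LTi cells, at 27.1 ± 18.4 against 1.403 ± 0.543. Among ILC2 genes, Rxrg (NM_009107), a retinoid X receptor, stood at 35.8 ± 11.6 against 0.142 ± 0.1097 RPKM and Il17rb (NM_019583), a subunit of the IL-25 receptor, at 28.9 ± 15.98 against 4.88 ± 0.531. Among ILC1 and NK cell genes, Ccl5 (NM_013653), a chemokine, rose to 247 ± 59.9 from 11.9 ± 6.82 RPKM and Tbx21 (NM_019507), which encodes T-bet, to 4.64 ± 0.6498 from 0.8397 ± 0.0999, while Prf1 (perforin) and Il18rap fell; Prf1 had no read in ChILP and 2.398 ± 1.89 RPKM in CLP. The median log2 fold changes were 2.12, 1.76 and 0.94, the last 1.16 with genes without a read in a group set at their bound. Leaving out a library moved the LTi and ILC3 median to 4.85 without CLP replicate 1, the ILC2 median to 2.81 without CLP replicate 1 and 0.98 without ChILP replicate 2 and the ILC1 and NK cell median to 1.84 without CLP replicate 1 and 0.50 without ChILP replicate 2. Camera called the 3 lists with a preset correlation (adjusted p = 3.84e-08, 3.56e-05 and 9.24e-04), and each had an adjusted p = 0.0527 with an estimated correlation. The LTi and ILC3 count was 5 without CLP replicate 1, 5 without CLP replicate 2 and 3 without ChILP replicate 2; that of ILC1 and NK cell genes was 2 higher and 1 lower without CLP replicate 1 and 4 higher and 1 lower without CLP replicate 2.

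Homing, cytokine and receptor genes changed in part, each count adjusted over its list alone (edgeR). Of 23 chemokine receptor and homing genes, 5 rose: Ccr8, Cxcr5, Ccr2, Cxcr6 and the gate gene Itgb7. Ccr8 (NM_007720), a chemokine receptor, had no read in CLP and 13.8 ± 1.93 RPKM in ChILP, at least 134-fold higher. Of 12 effector cytokine genes, Ccl5, Ltb and Lta rose. Ccl5 also stands in the ILC1 and NK cell list, and Ltb, Lta and Cxcr5 in the LTi and ILC3 list, so these results are not independent. The medians were 0.81 for homing (0.76 to 0.99 leaving out 1 library in turn) and 0.84 for effector cytokine genes (2.06 without CLP replicate 1, 1.64 without CLP replicate 2, 0.07 without ChILP replicate 1 and 1.30 without ChILP replicate 2). Both lists were called with a preset correlation (adjusted p = 3.60e-05 and 8.84e-04), and had an adjusted p = 0.0527 with an estimated correlation. Without CLP replicate 2 no homing gene passed, without ChILP replicate 2 2 rose, and without ChILP replicate 1 8 rose and 2 fell. Of 23 cytokine receptor genes Il2rb rose (3 rose without CLP replicate 2 and 3 without ChILP replicate 1, and 1 rose and 1 fell without ChILP replicate 2). Of 16 inhibitory and costimulatory receptor genes Pdcd1 rose and Cd27 fell (2 rose without CLP replicate 1, CLP replicate 2 or ChILP replicate 1, and none fell without CLP replicate 2 or ChILP replicate 2). Of 17 T lineage genes Bcl11b, Thy1 and Themis rose and Cd5 and Cd6 fell; only 2 rose and none fell without CLP replicate 2 or without ChILP replicate 2, 3 rose and none fell without ChILP replicate 1, and 3 rose and 1 fell without CLP replicate 1. Of 11 Notch targets Tcf7 and Gata3 rose and Notch1 (NM_008714) fell, from 34.6 ± 7.69 to 6.81 ± 2.05 RPKM. Of 10 MHC class II genes H2-Ob and H2-DMa fell, while the list's median was 0.48 (0.29 without ChILP replicate 2); without CLP replicate 1 4 rose and 2 fell, and without each other library in turn 1 fell. Cpa3 alone of 10 mast cell and basophil genes rose, and no gene of this list passed without any 1 of the 4 libraries; its median log2 fold change was 0.18 (-0.57 to 0.86 leaving out 1 library in turn) and its mean -0.55. The medians were 0.44 (0.14 to 0.72 leaving out 1 library in turn) for cytokine receptor, -0.47 (-0.36 to 0.05) for inhibitory and costimulatory receptor and 0.48 (0.05 to 0.74) for T lineage genes. Camera called none of the last 6 lists (lowest adjusted p = 0.122).

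No member passed, over its list alone (edgeR), among 30 proliferation genes, 18 myeloid progenitor genes, 13 erythroid and megakaryocyte genes, 9 plasma cell and mature B cell genes and 16 immediate early and stress genes; over all 13619 genes the unadjusted count was 792 and DESeq2's 263. The medians of these 5 lists each changed sign with a library left out. The medians, with the range leaving out 1 library in turn, were 0.05 (-0.02 to 0.19) for proliferation, 0.37 (-0.17 to 0.71) for myeloid progenitor and -0.09 (-1.21 to 0.04) for plasma cell and mature B cell genes. Immediate early and stress genes had a median of 0.47 (0.28 without CLP replicate 2, -0.40 without ChILP replicate 1 and 0.91 without ChILP replicate 2), and erythroid and megakaryocyte genes 0.48 (2.27 without CLP replicate 1, 0.19 without CLP replicate 2, -0.24 without ChILP replicate 1 and 0.95 without ChILP replicate 2). Camera with a preset correlation called only the erythroid and megakaryocyte list of these (adjusted p = 0.0360, and adjusted p = 0.703 with an estimated correlation), and not without CLP replicate 2 or ChILP replicate 1 (adjusted p = 0.973 and 0.699). Without ChILP replicate 2 camera also called the myeloid progenitor and the immediate early and stress lists higher (adjusted p = 0.0226 and 2.01e-04), though not with an estimated correlation (adjusted p = 0.683 and 0.554), and over their lists alone 2 erythroid and megakaryocyte genes rose and 2 plasma cell and mature B cell genes fell. Transcripts of mature marrow cells differed more within these groups than between them: Hba-a1 was higher in both number 1 libraries (CLP 3112 RPKM, ChILP 4547) than in both number 2 libraries (548 and 566).

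**Figure D2:**
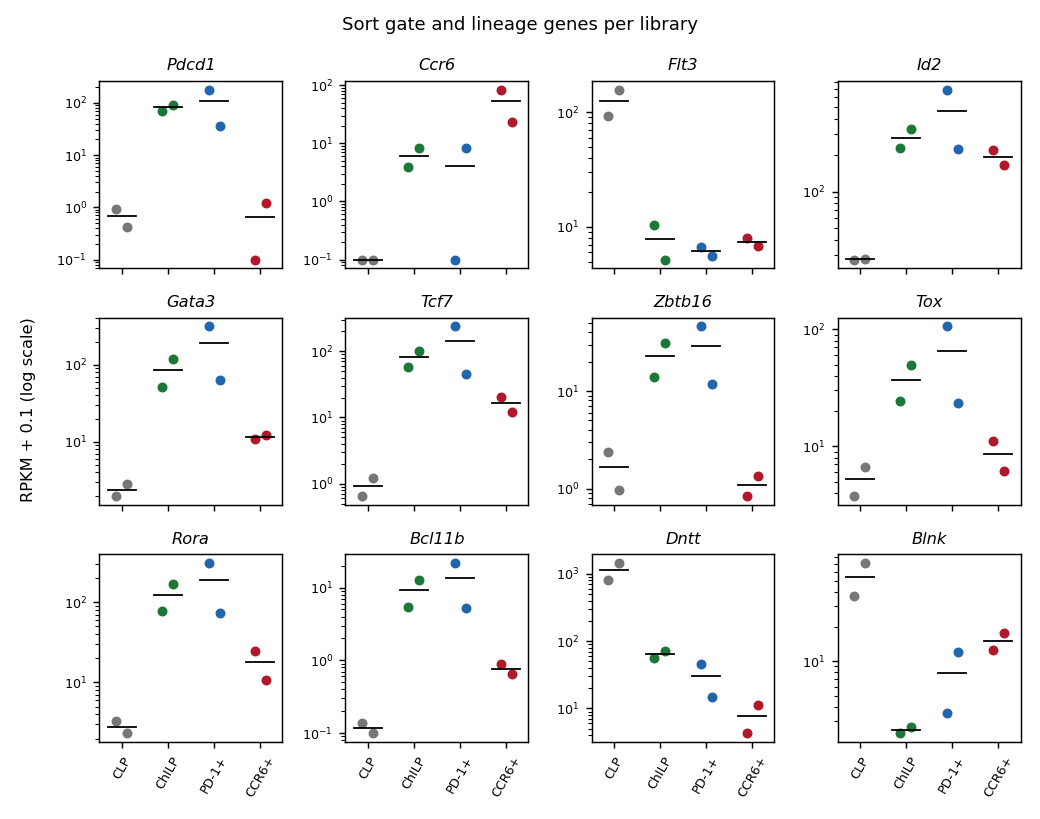
RPKM + 0.1 on a log scale of 12 genes in each library of the 4 groups; dots are single libraries and bars are group means. Gata3, Tcf7, Zbtb16, Tox, Rora and Bcl11b are higher in both ChILP and both PD-1+ libraries than in any CLP or CCR6+ library, and in PD-1+ cells 1 library lies below the other for each of them (316 and 62.8 RPKM for Gata3).

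The second comparison asked which genes set PD-1+ progenitors apart from CCR6+ progenitors. Most regulators of ILC progenitors were several-fold higher in PD-1+ cells, together with genes of ILC2, a list that shares Gata3, Rora, Bcl11b and Arg1 with the regulators. Gata3 stood at 189 ± 179 against 11.4 ± 0.812 RPKM, with 316 and 62.8 in the PD-1+ libraries and 10.8 and 11.97 in the CCR6+ libraries. Zbtb16 stood at 28.97 ± 24.3 against 0.983 ± 0.355 RPKM and Bcl11b at 13.4 ± 11.7 against 0.668 ± 0.174. Tcf7 stood at 142 ± 136 against 16.2 ± 5.87 RPKM (n = 2 each).

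Over all 13619 genes edgeR called 0, with 801 at an unadjusted p under 0.05 and a lowest adjusted p of 0.331. DESeq2 called 131, 99 higher and 32 lower in PD-1+ cells, but on simulated data for this comparison, drawn with edgeR's dispersions, 32.8% of its calls were wrong and it called 33.6 genes on average where nothing differed. Limma on log2(RPKM + 1) called 0. Without PD-1+ replicate 2 edgeR called 36 genes, 22 higher and 14 lower.

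Pdcd1, a gate gene, was higher in PD-1+ cells, adjusted over the list alone (edgeR), at 108 ± 102 against 0.551 ± 0.779 RPKM. Ccr6, the other gate gene, read 0 and 8.11 RPKM in the PD-1+ libraries and 84.2 and 23.6 in the CCR6+ libraries and did not pass (adjusted p = 0.243). The other 7 gate genes did not pass: log2 fold changes were -0.35 for Flt3, 0.47 for Il7r, 0.39 for Itga4, -0.14 for Itgb7, 0.51 for Kit, -0.76 for Ly6a and -0.35 for Il1rl1. The list's median was -0.14 (-0.42 to 0.31 leaving out 1 library in turn) and its mean 0.38. Without PD-1+ replicate 2, 1 gate gene was higher and 2 were lower.

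Of the 14 regulators, 10 were higher in PD-1+ cells, adjusted over the list alone (edgeR), and none lower, with a median log2 fold change of 2.92 (1.46 without PD-1+ replicate 1, where 12 of the 14 were above 0). They were Gata3 (log2 fold change 3.95, SE 0.72), Zbtb16 (4.77, SE 0.82), Bcl11b (4.23, SE 0.81), Rora (3.33, SE 0.72), Tcf7 (3.02, SE 0.70), Tox (2.82, SE 0.70), Id2 (1.16, SE 0.44), Arg1, Tox2 and Ets1. Nfil3 stood at 33.2 ± 3.102 against 30.6 ± 11.6 RPKM, and Runx3, Maf and Ikzf2 did not pass either. Camera called the list with a preset correlation (adjusted p = 1.30e-09), but not with an estimated one (adjusted p = 0.383). Id2 stood at 193 ± 40.4 RPKM in CCR6+ cells, against 27.6 ± 0.389 in CLP. These groups were enriched by different routes, and the difference was not tested. Transcripts of mature marrow cells moved with the replicates: from PD-1+ replicate 1 to replicate 2, Lyz2 stood at 6387 and 12900.0 RPKM while Gata3 stood at 316 and 62.8.

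Of 15 ILC2 genes, 7 were higher in PD-1+ cells, adjusted over the list alone (edgeR), and 1 was lower; none was lower without CCR6+ replicate 1 or CCR6+ replicate 2, and 3 were lower without PD-1+ replicate 2. Rxrg had 1 read in both CCR6+ libraries together and 98.1 and 13.4 RPKM in the PD-1+ libraries, a ratio of 2874 (95% counting interval 516 to 113600.0), of 719.9 without PD-1+ replicate 1 and of 5282 without PD-1+ replicate 2. Il17rb stood at 36.4 ± 35.6 against 1.69 ± 0.854 RPKM and Icos (NM_017480), a costimulatory receptor, at 25.03 ± 21.2 against 2.38 ± 0.118. Il2ra (NM_008367), a subunit of the IL-2 receptor, was the member lower in PD-1+ cells, at 0.174 ± 0.246 against 3.56 ± 0.761 RPKM. Il1rl1 and Klrg1, surface markers of mature ILC2, did not pass, and Il5, Il13 and Ptgdr2 were listed but not tested. Gata3, Rora, Bcl11b and Arg1 also stand among the regulators, so the results of these lists are not independent. The list's median log2 fold change was 2.41 (1.54 without PD-1+ replicate 1). Camera called the list with a preset correlation (adjusted p = 0.00789), not with an estimated one (adjusted p = 0.383), and not without PD-1+ replicate 2 (adjusted p = 0.104) or CCR6+ replicate 2 (adjusted p = 0.194).

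No member of the LTi and ILC3 list passed over the list alone (edgeR, lowest adjusted p = 0.170), but 10 of 15 had a negative log2 fold change and the median log2 fold change was -0.74 (-1.01 to -0.53 leaving out 1 library in turn). Lta (NM_010735), a lymphotoxin subunit, stood at 3.603 ± 0.945 against 14.3 ± 4.695 RPKM, Cd4 (NM_013488) at 9.79 ± 4.19 against 20.03 ± 8.73, Il1r1 at 0.765 ± 0.656 against 2.46 ± 0.324 and Il23r, a subunit of the IL-23 receptor, at 0.305 ± 0.116 against 2.16 ± 1.26. Other members ran the other way in their means. Cxcr5 stood at 62.98 and 10.5 RPKM in the PD-1+ and 17.78 and 13.09 in the CCR6+ libraries. Ltb stood at 493.7 and 256.2 against 363.5 and 266.7 RPKM, and Ahr at 7.19 and 4.40 against 1.31 and 3.27. Camera called the list lower in PD-1+ cells with a preset correlation (adjusted p = 0.00143), but not with an estimated one (adjusted p = 0.383) and not without PD-1+ replicate 2 (adjusted p = 0.0707), where 2 members were lower over the list alone.

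Single genes of further lists were higher in PD-1+ cells over their list alone (edgeR); of these, Pdcd1 was a gate gene and its difference follows the sort. Of 11 Notch targets, Hes1 (NM_008235), a repressor induced by Notch signalling, stood at 46.7 ± 39.6 against 3.24 ± 3.04 RPKM and was higher with Gata3 and Tcf7; the list's median log2 fold change was -0.22 (-0.47 to 0.00 leaving out 1 library in turn) and its mean 0.77. Without PD-1+ replicate 2, 3 Notch targets were higher and 2 lower, and without PD-1+ replicate 1 3 were higher and 1 lower. Bcl11b and Thy1 were higher of 17 T lineage genes (1 without PD-1+ replicate 1, none without CCR6+ replicate 1 or CCR6+ replicate 2, 6 higher and 1 lower without PD-1+ replicate 2). Pdcd1, Cd27 and Icos were higher of 16 inhibitory and costimulatory receptor genes (1 without PD-1+ replicate 1, CCR6+ replicate 1 or CCR6+ replicate 2). Il17rb was higher of 23 cytokine receptor genes (none without PD-1+ replicate 1, CCR6+ replicate 1 or CCR6+ replicate 2, and 3 higher and 4 lower without PD-1+ replicate 2). The medians were 0.47 (0.01 to 0.79 leaving out 1 library in turn) for T lineage, 0.31 (0.30 to 0.71) for inhibitory and costimulatory receptor and -0.20 (-0.17 to 0.07) for cytokine receptor genes. Camera with a preset correlation called none of these 4 lists (lowest adjusted p = 0.0915), but without CCR6+ replicate 1 it called the inhibitory and costimulatory list higher (adjusted p = 0.0205), though not with an estimated correlation (adjusted p = 0.624).

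A further 4 lists stood slightly lower in PD-1+ than in CCR6+ cells. No member passed over its list alone (edgeR), but camera with a preset correlation called all 4: 30 proliferation genes (median log2 fold change -0.31, adjusted p = 0.00116), 18 myeloid progenitor genes (-0.34, 0.0275), 13 erythroid and megakaryocyte genes (-0.45, 0.0275) and 10 MHC class II genes (-0.66, 0.0390). Which cells carried these transcripts was not tested. With an estimated correlation the adjusted p = 0.566, 0.701, 0.695 and 0.483. Leaving out a library moved the median of myeloid progenitor genes to 0.11 without PD-1+ replicate 1, -1.02 without PD-1+ replicate 2, -0.62 without CCR6+ replicate 1 and 0.10 without CCR6+ replicate 2, that of MHC class II genes to -0.29 without PD-1+ replicate 1 and -1.24 without PD-1+ replicate 2, that of proliferation genes to -0.19 without CCR6+ replicate 1 and that of erythroid and megakaryocyte genes to -0.29 without CCR6+ replicate 1. The proliferation call ended without CCR6+ replicate 1 (adjusted p = 0.111), and the myeloid call without PD-1+ replicate 1 (0.752) or CCR6+ replicate 2 (0.593). The erythroid and the MHC class II calls each ended without any 1 of the 4 libraries (lowest adjusted p = 0.0803 and 0.0502). Without PD-1+ replicate 2, 7 myeloid progenitor and 3 MHC class II genes were lower over their lists alone. In the remaining 9 lists no member passed and none was called; their medians are given with the range leaving out 1 library in turn. The median log2 fold change was -0.35 (-0.75 to -0.10) for 18 B lineage genes (mean 0.29), -0.17 (-0.28 to -0.13) for 16 stem and multipotent progenitor genes, -0.34 (-0.43 to -0.15) for 12 plasmacytoid and dendritic cell genes and 0.18 (0.17 to 0.43) for 25 ILC1 and NK cell genes. It was -0.06 (-0.26 to 0.09) for 23 chemokine receptor and homing genes (mean 0.13), 0.04 (-0.51 to 0.76) for 12 effector cytokine genes (placed lower by camera), -0.28 (-0.64 to 0.39) for 10 mast cell and basophil genes (mean 0.21) and -0.36 (-0.92 to -0.08) for 9 plasma cell and mature B cell genes. Immediate early and stress genes (16) had a median of -0.12 (-0.87 to 0.39), and camera called them lower without CCR6+ replicate 1 (adjusted p = 0.0167), though not with an estimated correlation (adjusted p = 0.624). Over the lists alone, leaving out PD-1+ replicate 2 gave 1 higher and 1 lower B lineage gene, 1 lower stem and multipotent progenitor gene, 1 higher and 3 lower plasmacytoid and dendritic cell genes, 3 higher and 1 lower ILC1 and NK cell genes and 2 lower homing genes. Without CCR6+ replicate 2, 1 mast cell and basophil gene was higher.

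Among DESeq2's 32 genes higher in CCR6+ cells, chosen after their values were seen, Serinc2 (NM_001253386) and Gdpd5 (NM_201352) had no read in PD-1+ cells. They stood at 7.74 ± 4.96 and 4.28 ± 3.696 RPKM in CCR6+ cells, at least 149-fold and at least 157-fold higher (at least 81.7-fold and at least 61.2-fold without CCR6+ replicate 1, and at least 253-fold for Gdpd5 without CCR6+ replicate 2), with edgeR adjusted p = 0.359 and 0.331. Among its 99 genes higher in PD-1+ cells, Bcas1 (NM_029815) had no read in CCR6+ cells and 16.5 ± 13.8 RPKM in PD-1+ cells, at least 429-fold higher, at least 176-fold without PD-1+ replicate 1 and at least 682-fold without PD-1+ replicate 2 (edgeR adjusted p = 0.331).

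**Figure D3:**
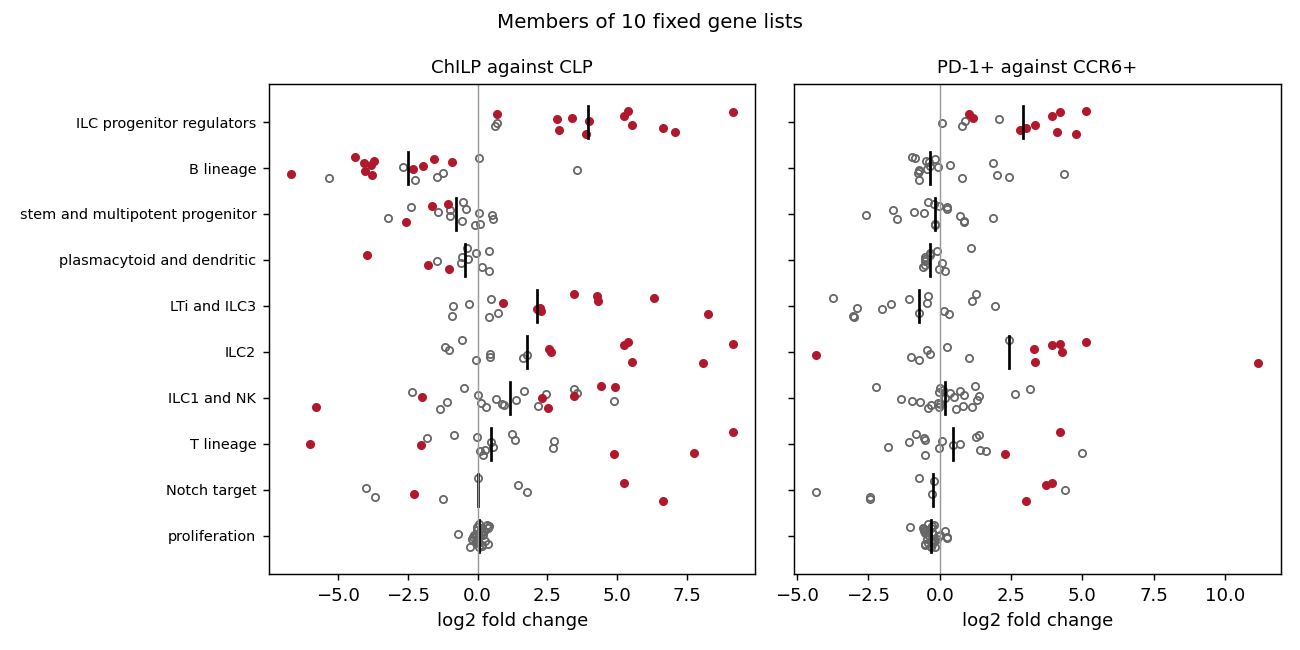
Log2 fold change (x axis) of each tested member of 10 gene lists fixed before the data were examined, for ChILP against CLP (left) and PD-1+ against CCR6+ (right); filled red dots passed edgeR's test adjusted over the list alone, open dots did not, and bars are medians with genes without a read in a group set at their bound. Of 14 regulators, 12 are filled on the left and 10 on the right, all above 0, and 11 of 18 B lineage genes are filled on the left, all below 0.

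The comparisons share no library, but all 8 libraries were fitted together, so the 2 sets of calls rest on shared dispersions, which can raise the number of genes called in both in any direction. As edgeR called 0 genes in the second comparison (801 at an unadjusted p under 0.05; DESeq2 131), the planned overlap was 0 by construction, and the sets and tests below were chosen after values were seen. Of the 115 genes DESeq2 called higher in ChILP and the 99 it called higher in PD-1+ cells, 29 were shared, where 0.836 would be expected from independent lists (two-sided Fisher exact test over genes, adjusted p = 3.67e-37). They included Gata3, Tcf7, Zbtb16, Tox, Rora, Bcl11b, Arg1, Il17rb, Rxrg and Pdcd1. Only Serinc2 was called higher in both ChILP and CCR6+ cells (expected 0.270, Fisher exact test, adjusted p = 0.238), while 4 genes, Dntt, Myl10, Neurl1a and Tmem121, were higher in CLP and PD-1+ cells (expected 1.08, adjusted p = 0.0455) and 2, Klhl30 and Sdc4, in CLP and CCR6+ cells (expected 0.348, adjusted p = 0.0627). With edgeR's genes at an unadjusted p under 0.05 the 4 counts were 75, 11, 29 and 16, with 15.5, 6.86, 16.8 and 7.44 expected (Fisher exact test, adjusted p = 1.26e-30, 0.114, 0.00645 and 0.00645). All 8 counts lay above the expected number, opposite directions included, so the excess is not read as a shared program. The direction among DESeq2's shared genes, 29 of 30 against 4 of 6 higher in PD-1+ cells, did not pass (two-sided Fisher exact test over genes, p = 0.0658). With edgeR's genes the counts were 75 of 86 and 29 of 45 (Fisher exact test, p = 0.00318). Of all genes DESeq2 called higher in ChILP, 79 of 115 had a positive log2 fold change in the second comparison, against 69 of 148 of those it called higher in CLP (Fisher exact test, p = 4.34e-04); from reads per library the counts were 81 and 73, and 68 and 68 without PD-1+ replicate 1 (p = 0.0355), the highest p of the 4 leaving out a library. Genes are not independent replicates, so these p-values describe the lists.

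Positions were read on a line from the CCR6+ mean (0) to the PD-1+ mean (1). The line was to be drawn over edgeR's called genes, of which there were none, so DESeq2's 131 genes were used. Genes picked as low in 1 group place other groups toward the higher one, and ChILP and CLP both lay on that side in each direction, so the positions do not say which population ChILP resembles, and a position pooled over genes depends on how many genes of each direction the set holds. The pooled median position was 0.727 and 0.966 for the ChILP libraries and 0.353 and 0.420 for the CLP libraries. Over the 99 genes higher in PD-1+ cells it was 0.798 and 1.01 for ChILP and 0.644 and 0.696 for CLP, and over the 32 genes higher in CCR6+ cells, among them Serinc2 and Gdpd5, -0.0632 and 0.0735 for ChILP and -0.195 and -0.0256 for CLP. Over the 183 genes with an edgeR unadjusted p under 0.01, the CLP positions were 0.645 and 0.716 and the ChILP positions 0.806 and 0.995. The route of enrichment differs between the groups placed and those that define the line, with Lyz2 and Hba-a1 higher in every PD-1+ and CCR6+ library, so the positions are descriptions with no test.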

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

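At 7685188 to 13997897 reads and 2 libraries per group, edgeR's simulated recovery of 4-fold changes was 42.2% for ChILP against CLP and 43.6% for PD-1+ against CCR6+. The cause of the shifts below was not tested unless given.

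The count of genes called between ChILP and CLP was 3 in the planned edgeR fit, 0 with DESeq2 size factors, 263 with DESeq2, 55 and 47 with limma on log2(RPKM + 1) and log2(RPKM + 0.1), 63 without a filter, 15 with the 5 RPKM filter (fewer genes tested), 59 from the 4 libraries compared and 0 at an adjusted p under 0.01. Alternatives chosen after seeing the data gave 31 with voom library weights and 34 with the covariate for mature myeloid transcripts, and 3 with the longest transcript or without genes at several loci. The 3 genes were also called by DESeq2, limma with a pseudocount of 0.1, both filters and the 4 libraries alone. Leaving out each library in turn gave 0 to 24 genes. Higher calls made up 18 of limma's 55, 25 of 47 with the smaller pseudocount, 22 of 63 without a filter, 8 of 15 with the stricter filter, 27 of 59 from the 4 libraries, 21 of 34 with the covariate, 15 of 24 without ChILP replicate 1 and only 3 of 31 with voom weights.

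Between PD-1+ and CCR6+ cells the count was 0 in the planned fit (801 at an unadjusted p under 0.05) and 131 with DESeq2. It was 0 to 36 leaving out each library in turn, the highest without PD-1+ replicate 2, and 5 without both number 2 libraries, an alternative chosen after seeing the data. All other settings gave 0 (437 to 883 genes at an unadjusted p under 0.05). Median log2 fold changes of all genes lay within 0.1 of 0 in every setting.

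Replicate numbers are shared by the groups, but over all genes libraries with the same number deviated together only weakly (correlation over genes of the number 1 minus number 2 difference 0.094 for CLP with ChILP, 0.080 for PD-1+ with CCR6+). Some transcripts of mature marrow cells did move together within a comparison. Hba-a1 was higher in both number 1 libraries of CLP and ChILP. All 14 neutrophil genes were higher in number 2 of PD-1+ and of CCR6+ cells (median log2 ratios 1.02 and 1.01). Red cell genes did not move alike there (0.44 and -0.10). With 2 libraries per group the numbers cannot be shown to pair the libraries. The replicate block over all 8 libraries gave 0 genes in ChILP against CLP and 0 in PD-1+ against CCR6+. It fits 1 number effect for all groups, but the covariate for mature myeloid transcripts ran in opposite ways. From number 1 to number 2 it fell from -0.50 to -3.01 in CLP and from -0.14 to -2.92 in ChILP. It rose from 1.03 to 2.06 in PD-1+ and from 1.35 to 2.13 in CCR6+ cells. This block therefore cannot weigh a pairing within each comparison. With the block in the 4 libraries alone, a setting chosen after seeing the data, the counts were 112 and 0, against 59 and 0 without it. With the block over all 8 libraries camera with a preset correlation called 10 and 7 lists, as without it, but fry called 0 and 0 (lowest adjusted p = 0.0511 and 0.0900).

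Camera with an estimated correlation called 0 lists in either comparison, against 10 and 7 with the preset one. Fry called 8 lists in ChILP against CLP and 2 in PD-1+ against CCR6+ (ILC2 and Notch target, adjusted p = 0.0112 and 0.00634). Leaving out each library gave 9 to 12 and 3 to 6 lists with camera's preset correlation, and 1 to 9 and 0 to 1 with fry. Adjusted over the list alone, the number of regulators called was 10 to 12 and 7 to 12 over all settings (12 and 10 as planned), without regard to which genes they were. B lineage gave 6 to 14 (main 11). LTi and ILC3 in ChILP against CLP (main 9) gave 5 without a filter, 4 from the 4 libraries, 4 with the block, 2 with voom weights, 5 with the 4 libraries and the block, and 3 to 8 leaving out a library. ILC2 in PD-1+ against CCR6+ (main 8) gave 5 with voom weights. The overlap of calls was 0 as planned, 36 genes from DESeq2 calls and 131 from edgeR's unadjusted p under 0.05. Positions moved to 0.288, 0.304, 0.705 and 0.958 (CLP 1, CLP 2, ChILP 1, ChILP 2) over the 97 DESeq2 genes changed at least 8-fold, and leaving out a library gave 0.281 to 0.432, 0.389 to 0.543, 0.607 to 0.917 and 0.771 to 1.17.

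Of 305 values of 18 named genes in ChILP against CLP, 244 kept direction and side of the threshold, 46 passed where the planned fit did not, 11 no longer passed and 4 changed sign. Of 305 values of 17 genes in PD-1+ against CCR6+ the numbers were 283, 13, 0 and 9. The sign changes were in genes that did not pass over all genes in the planned fit. In ChILP against CLP, leaving out a library moved Il7r from -0.09 to between -0.60 and 0.29 and Il1rl1 from 0.44 to between -0.43 and 1.16 on the log2 scale. In PD-1+ against CCR6+ the ranges were -0.56 to 1.18 for Il7r, -0.34 to 0.088 for Itgb7, -5.51 to 0.61 for Il1rl1, -0.58 to 1.34 for Kit and -0.27 to 0.50 for Nfil3.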

Other observations

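Some genes of the response to interferon gamma were lower in ChILP than in CLP, among them 4 of 7 guanylate binding protein genes listed, while Gbp2, Gbp3 and Gbp7 did not pass (Gbp2 7.32 ± 2.63 RPKM in ChILP and 8.86 ± 4.67 in CLP). Gbp4 stood at 0.912 ± 0.512 RPKM in ChILP and 6.58 ± 2.75 in CLP, Gbp9 at 0.479 ± 0.230 and 4.23 ± 1.11, Gbp6 at 0.820 ± 0.370 and 5.40 ± 2.71, and Nlrc5, a regulator of MHC class I genes, at 2.33 ± 0.286 and 5.69 ± 0.140 (n = 2 each). Gbp11 had no read in ChILP and 2.98 ± 0.109 RPKM in CLP. In a list of 18 genes of this response, written after these values had been seen, 5 fell and Socs1, a feedback inhibitor of cytokine signalling, rose (82.1 ± 20.5 against 24.3 ± 12.3 RPKM), adjusted over the list alone with edgeR, and camera gave an adjusted p = 1.79e-07 with the preset and 0.0616 with an estimated correlation. The hypothesis that the response differs as a set was tested on the 13 members not seen before, after the values were known: none passed over that list alone, camera gave an adjusted p = 0.0154 with the preset and 0.25 with an estimated correlation, and the median log2 fold change was -0.36, so it stays open. For 32 interferon-stimulated genes, some of them also seen before, the adjusted p was 3.58e-05 with the preset and 0.23 with an estimated correlation, and the median -0.42. In PD-1+ against CCR6+ cells no member of either list passed over its list alone (edgeR), and camera gave the interferon-stimulated list an adjusted p = 0.0055 with the preset correlation (27 of 32 below 0) and 0.783 with an estimated one, and the guanylate binding list 0.774 and 0.854.

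The tests of the next 2 patterns were all chosen after the data had been seen; those of the undepleted suspension and of CCR6+ RNA in PD-1+ replicate 2 were written before the values they measure were known, the others after. For the progenitors' own transcription and for CCR6+ RNA the rule for reading the test was narrowed after the values were seen, in both cases towards leaving the question open.

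Transcripts of mature marrow cells were higher in the PD-1+ and CCR6+ libraries than in the CLP and ChILP libraries, although every sort was gated on lineage-negative cells. Sequencing depth is argued against as a cause, since the ratio of mean reads was 0.95. The undepleted marrow suspension is a candidate source. Neutrophil genes not looked at before were higher by a median of 2.43 on the log2 scale (14 genes). Red cell genes were higher by 1.42 (12 genes, Car1 against the rest at -2.23), and lineage-negative progenitor genes lower (median -0.91, 14 genes). All of these genes reached 1 RPKM in a CLP or ChILP library and none stood in the lists fixed before. Retnlg, a neutrophil gene, stood at 25.4 to 281.9 RPKM in CLP and ChILP and 281.9 to 983.6 in the other libraries. The neutrophil and red cell lists mark cell types whose transcripts had already been seen to be high. They therefore repeat the pattern and do not show its source. Transcription by the sorted progenitors themselves cannot be told apart from RNA of the suspension. Between the libraries of a group mature marrow genes and regulators moved apart by at least 1.04 on the log2 scale. However, the regulators' median in CCR6+ cells (-0.41) lay within its SD (0.79). Experiment and route of enrichment change together, and a biological difference between total ChILP and its subsets was not tested apart from them.

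PD-1+ replicate 2 held less of the regulators than PD-1+ replicate 1 (median log2 ratio -2.00, SD 0.71, 14 genes) and was closer to CCR6+ replicate 2 than to its own replicate. An exchange with CCR6+ replicate 2 is argued against, since 2 of the 14 regulators were higher in CCR6+ replicate 2. A smaller share of progenitor RNA is a candidate explanation: of 112 of the 115 genes that DESeq2 called higher in ChILP than in CLP, those with at least 1 RPKM in a PD-1+ library, 87.5% were lower in PD-1+ replicate 2, with a median log2 ratio of -1.29. They include the regulators Gata3, Tcf7, Zbtb16, Tox, Tox2, Rora, Bcl11b and Arg1, so this result in part repeats the pattern. Replacement of progenitor RNA by 1 unchanged mixture of other cells did not pass its rule. Neutrophil genes rose more than red cell genes by 0.58 on the log2 scale, above their pooled SD of 0.39. The lists also parted from CCR6+ replicate 1 to replicate 2 (medians 1.01 and -0.10), so the gap is not particular to PD-1+ replicate 2. The SD is a spread over genes, not over libraries, so the test does not decide the question. CCR6+ RNA mixed into PD-1+ replicate 2 cannot be told apart from other marrow RNA. The 89 genes tested were at least 16-fold (CCR6+ replicate 1) and at least 4-fold (CCR6+ replicate 2) higher than in PD-1+ replicate 1. Each had at least 2 RPKM in both CCR6+ libraries. In PD-1+ replicate 2 they stood at a median of 78.4% of their CCR6+ replicate 2 level, and 26 neutrophil and red cell genes at 92.2%. Genes picked as low in PD-1+ replicate 1 can lie higher in any other library, so the 78.4% does not decide the question. Single genes of the 89 ran both ways. Without a read in PD-1+ replicate 2 were 5, among them Serinc2 with 116 reads in CCR6+ replicate 2. Ccr6 had no read in PD-1+ replicate 1 and 205 in PD-1+ replicate 2 (8.11 RPKM, against 23.6 in CCR6+ replicate 2). A difference between mice was not tested, as the labels do not name them.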
